A study of Mus musculus with 18 samples.

How the data were processed

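RNA from the liver of 18 mice (8 on linseed oil, 10 on palm oil) was measured on 1-colour Agilent arrays, 1 array per mouse, with 1 µg of total RNA labelled with Cy3, per the labels' protocols. The diets gave 16.7% of energy as protein, 32.1% as carbohydrate and 51.1% as lipid. Groups were taken from the sample titles. Per the file headers, the arrays were read on a GenePix scanner and the spot intensity values were extracted by the authors with Agilent Feature Extraction 9.5.3.1, whose processed signal is background-subtracted within the array and not scaled between arrays. The submitters' processing notes name Feature Extraction 9.5 and limma, with no version. The deposited value table of the authors holds log2 values of 18060 probes on the same arrays. Their rank correlation was 0.999975 to 0.999996 with the median spot signal and 0.991 to 0.998 with the processed signal, the medians per array were 7.8476 to 7.8519, and genes were not centred. How that table was scaled and filtered is not given in the sources used here, and it served as an alternative only.

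Each array held 44397 spots and 39429 non-control probes, of which 399 had 10 spots each. Values were log2 of the processed signal minus each array's 75th percentile, taken over non-control probes (117 to 204 intensity units). Spots that the image software marked as non-uniform or as population outliers (238 to 1703 per array) were then left out, saturated spots (63 to 111 per array) were kept, and spots of a probe were averaged. A first version of the scaling took the percentile after leaving out marked spots. It was replaced, after both counts of called genes had been seen, because the design fixed beforehand named non-control probes; the first version gave 42 genes against 121 and is kept among the alternatives. Marked spots were mostly bright: 81.3% of genes in the brightest decile had one, against 4.14% of the others, and 593 genes could not be tested because of them.

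A probe was kept if it was well above background on at least 8 arrays and had a value on at least 6 arrays of each group. The brightest kept probe stood for a gene; 3043 genes had several. Among named genes, another kept probe differed in sign for Cpt1a, Fads2 and Rps3, none of them called. Fold changes are on the log2 scale of these values. Probe names were updated through a RefSeq table of assembly GRCm38.p6, used for names only: 26055 probes were matched by accession, 3195 by symbol and 930 by synonym, and 9249 kept the file's name. Probe positions are those of the file headers' annotation, mm9.

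Diets were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates, Benjamini-Hochberg adjusted p under 0.05). A set of 35 gene lists (9 of markers of other cells and tissues) was written before the data were examined, as were the design, the alternatives and the rule for named genes. Lists were tested with camera (preset correlation 0.01), with camera at an estimated correlation and with fry, adjusted over the lists. An adjusted p given for a list is from camera at the preset correlation unless the sentence names another. Missing values were filled with group means for the list tests only. Named genes are the 8 largest rises and 8 largest falls among called genes with a symbol, up to 3 called members of each list with the smallest adjusted p (or the 1 member with the smallest p), and 22 anchor genes of lipid metabolism; some genes that the rule names are not reported here. On simulated data with the arrays' own spread, the procedure called 95% of genes changed by 1 log2 unit, 56% of those changed by 0.5, and 11 of 15751 unchanged genes. The simulated noise was independent, without slide effects, correlation between genes or missing values, so these rates need not hold on the real arrays.

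Slides (5, each with both diets) coincided with scan groups. The headers gave no barcode for the arrays of slide 1, which were taken to be on the same slide. Residual structure followed slides: slide accounted for a share of 0.941 of the variance of the first principal component of the residuals. Slide was therefore tried as a fixed block and a random block (consensus correlation 0.216), and differences were taken within slides. Alternatives were normexp background correction with an offset of 50, quantile and other scalings, no filter or a stricter filter on dim probes, marked spots kept, the mean of a gene's probes, every probe on its own, the replicate number as a block, trend and robust eBayes, array weights, the authors' value table, a change of at least 1.5-fold, and leaving out each array. Scaling over unmarked spots, leaving out slides 4 and 5 (the most marked spots) and leaving out slide 1 (the fewest probes above background) were added after the data had been seen. Control spots were left out.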

Results

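Liver gene expression was measured in 18 male C57BL/6J mice, an inbred laboratory strain, after 5 weeks on a high-fat diet that held either linseed oil (8 mice) or palm oil (10 mice). Mice were 8 weeks old at the start and 13 weeks old at the end, and had been assigned to the diets at random. Linseed fat was 66.7% polyunsaturated, of which alpha-linolenic acid (49.7%) made up most, with 9.7% saturated fatty acids. Palm fat was 55.6% saturated and 8.8% polyunsaturated. Each liver was hybridised to its own 1-colour array of 39429 non-control probes, of which 17258 to 22445 per array were well above background. The number of arrays and the signal over background limit the precision. The comparison asks how liver expression differs between fat rich in an n-3 fatty acid precursor and fat rich in saturated fatty acids. Differences are linseed minus palm on the log2 scale, ± SE from limma, with Benjamini-Hochberg adjusted p.

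Fatty acid oxidation genes and a set of cytochrome P450 genes rose on linseed oil. Cyp3a16 was 4.96-fold higher (2.31 ± 0.18, adjusted p = 1.51e-06) and Cyp3a11, the main drug-metabolising Cyp3a enzyme of mouse liver, 4.45-fold higher (2.15 ± 0.16, adjusted p = 2.62e-06). Acot3, a peroxisomal acyl-CoA thioesterase, was 3.76-fold higher (1.91 ± 0.31, adjusted p = 0.0044) and Cidec, a protein that enlarges lipid droplets, 4.03-fold higher (2.01 ± 0.36, adjusted p = 0.0114). Tff3, a secreted trefoil peptide, was 5.64-fold lower on linseed oil (−2.50 ± 0.31, adjusted p = 0.000622, n = 7 linseed and 10 palm). Its difference was −2.19 ± 0.39 with marked spots kept (adjusted p = 0.00848). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 2-fold lower (−0.998 ± 0.22, adjusted p = 0.0389), a call kept in 22 of 38 settings. Of 15951 genes tested, 121 passed an adjusted p of 0.05, 91 higher and 30 lower on linseed oil; 1621 genes had an unadjusted p under 0.05. Changes were mostly small: 33 of the called genes reached 2-fold, and their median absolute difference was 0.62.

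The 5 slides each held both diets, so the comparison was repeated with slide as a fixed block and within slides. With slide as a fixed block 131 genes passed (93 higher, 38 lower), 95 of them among the 121. With slide as a random block 200 passed (146 higher, 54 lower), among them all 121. Of the 110 called genes measured on all 5 slides, 106 differed in the same direction within each slide; these genes had been chosen on the same arrays, and of all genes 58.9% to 73.0% kept their direction within a single slide. The keratin Krt23 was an exception among the called genes, at −0.095 within slide 5. The count depended on the processing: scaling over unmarked spots gave 42 genes, another background correction 68, no filter on dim probes 44, a minimum change of 1.5-fold 63, the arrays without slides 4 and 5 21, and those without slide 1 30. Leaving out linseed replicate 2, 3, 5 or 7 gave 63, 60, 51 or 62 genes, and leaving out palm replicate 1, 5, 6, 9 or 10 gave 66, 63, 78, 64 or 71.

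Genes of peroxisomal beta-oxidation, which shortens very long and polyunsaturated fatty acids, rose as a group. Of 25 tested members 6 rose and none fell; adjusted over the list alone, 13 rose and 0 fell. The list's mean was 0.41 higher on linseed oil, and the difference held with an estimated correlation (adjusted p = 0.0012; 0.0232 with slide as a fixed block). It was higher in 5 of 5 slides, by 0.32 to 0.60. Beside Acot3, Ehhadh, the peroxisomal bifunctional enzyme, rose 1.78-fold (0.83 ± 0.14, adjusted p = 0.00446). Acaa1b, a peroxisomal thiolase, rose 1.70-fold (0.76 ± 0.11, adjusted p = 0.00438, n = 7 linseed and 8 palm).

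Other targets of PPARalpha, the nuclear receptor that senses fatty acids in liver, rose in the same arrays. Of 27 tested members 7 rose and 0 fell; adjusted over the list alone, 16 rose and 1 fell. The mean was 0.46 higher (adjusted p = 0.00297 with an estimated correlation, 0.0288 with slide as a fixed block), and higher in 5 of 5 slides. Cyp4a10, a fatty acid omega-hydroxylase whose probe also lists Cyp4a32, rose 3.01-fold (1.59 ± 0.23, adjusted p = 0.00217). Signal shared between the Cyp4a probes was not checked. Cyp4a31 of the same family rose 2.71-fold (1.44 ± 0.21, adjusted p = 0.00217), and Acot2, a mitochondrial acyl-CoA thioesterase, rose 2.25-fold (1.17 ± 0.17, adjusted p = 0.00186; above background on 7 linseed and 6 palm arrays), a call kept in 35 of 36 settings and lost with normexp background correction (0.15, adjusted p = 0.999). Ppara itself did not pass (0.29 ± 0.09, adjusted p = 0.165), and was at 0.15 ± 0.07 with marked spots kept (adjusted p = 0.455). Pdk4, a kinase that restrains glucose oxidation, differed by 0.76 ± 0.23 (adjusted p = 0.192) and the hormone gene Fgf21 by 0.26 ± 0.20 (adjusted p = 0.726). Neither passed. Cyp4a14 and Angptl4 could not be tested because too many of their spots were marked by the image software. With marked spots kept, Cyp4a14 was 7.59-fold higher on linseed oil (2.92 ± 0.34, adjusted p = 0.000205) and Angptl4 differed by 0.10 ± 0.21 (adjusted p = 0.918).

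Mitochondrial beta-oxidation and ketogenesis shifted by a smaller amount. Of 14 tested members 1 rose and 0 fell, and adjusted over the list alone 11 rose. Marked spots kept other members of the list from being tested. With those spots kept, 22 members were tested, 7 rose and 0 fell, and the mean was 0.28 higher. The mean was 0.26 higher (adjusted p = 0.0067 with an estimated correlation, 0.0288 with slide as a fixed block), and higher in 5 of 5 slides, by 0.073 to 0.43. With marked spots left out, the called member was Slc25a20, the carrier of acylcarnitines into mitochondria (1.37-fold, 0.45 ± 0.09, adjusted p = 0.0246). Cpt1a, the enzyme that commits fatty acids to mitochondria, did not pass (−0.02 ± 0.10, adjusted p = 0.972), and was 0.015 ± 0.09 with slide as a fixed block. Subunits of oxidative phosphorylation had no called member among 53. Their mean was 0.09 higher, a call that was lost with an estimated correlation (adjusted p = 0.574); the sign turned within slides 2 and 5.

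**Figure D1:**
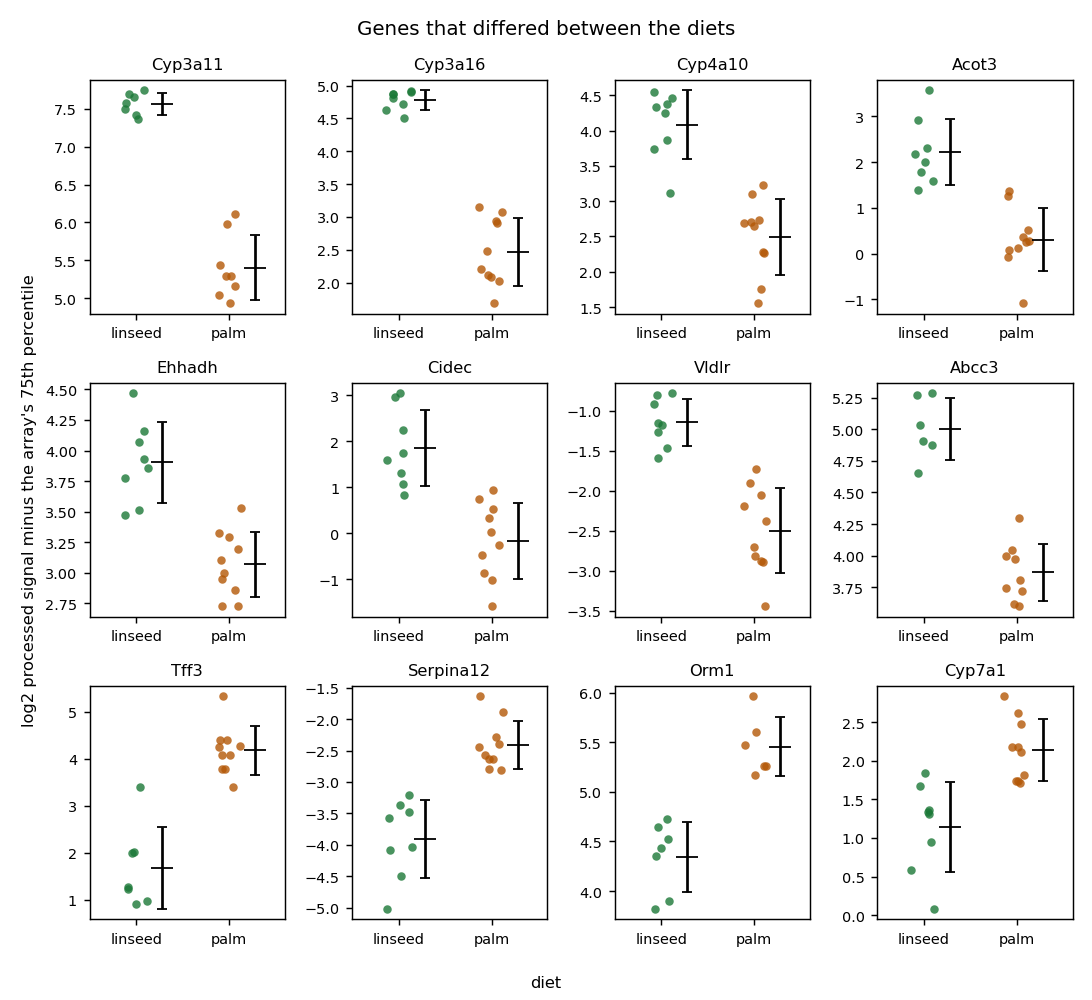
Each point is 1 array's log2 processed signal minus that array's 75th percentile (vertical axis, log2 units, scaled separately in each panel and not starting at 0) for 12 called genes on linseed and palm oil; the bar marks the mean ± SD. Cyp3a11, Cyp3a16, Acot3, Vldlr and Abcc3 do not overlap between the diets on the higher side, and Tff3, Serpina12 and Orm1 do not overlap on the lower side. Marked spots are left out, so the separation of Tff3 covers 7 of 8 linseed arrays. It does not hold with the marked spot kept, which lay near the palm mean. That of Cyp3a11, Abcc3 and Orm1 likewise covers only part of the arrays.

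Further Cyp3a genes, which encode enzymes that oxidise drugs and steroids, rose beside Cyp3a16 and Cyp3a11. Cyp3a41b rose 5.01-fold (2.33 ± 0.20, adjusted p = 2.62e-06; its probe also lists Cyp3a41a) and Cyp3a59 2.78-fold (1.48 ± 0.14, adjusted p = 6.06e-06). Cyp3a57, chosen after its values were seen, rose 1.45-fold (0.53 ± 0.12, adjusted p = 0.0401), a call kept in 11 of 38 settings and not with slide as a fixed block (adjusted p = 0.0618), but with slide as a random block (adjusted p = 0.0205). In mm9 coordinates, the probes lie on chromosome 5 at 146319794 to 146319853 (Cyp3a41b), 146197274 to 146197333 (Cyp3a16), 146666237 to 146666296 (Cyp3a11) and 146920638 to 146920697 (Cyp3a59). Mean log2 values of Cyp3a11 were 7.56 ± 0.14 (SD, n = 7) on linseed and 5.41 ± 0.42 (SD, n = 8) on palm oil. The wider list of xenobiotic metabolism genes, targets of the receptors CAR and PXR, had 4 of 28 members higher and 0 lower; adjusted over the list alone, 5 rose and 1 fell. Its mean was 0.32 higher, and its call was lost with an estimated correlation (adjusted p = 0.119) but kept with fry (adjusted p = 0.0012).

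Genes of oxidative stress defence and glutathione metabolism, targets of NRF2, rose as a group. Of 38 tested members 4 rose and 0 fell; adjusted over the list alone, 8 rose. The mean was 0.25 higher in the arrays of linseed oil (adjusted p = 0.0429 with an estimated correlation, but 0.124 with slide as a fixed block), and higher in 5 of 5 slides. Gsta1, a glutathione transferase, rose 2.46-fold (1.30 ± 0.26, adjusted p = 0.028), Ephx1, microsomal epoxide hydrolase, 1.71-fold (0.78 ± 0.14, adjusted p = 0.0114), and Nqo1, a quinone reductase, 1.52-fold (0.61 ± 0.13, adjusted p = 0.0301). Gsta1 kept its call in 27 of 38 other settings, Ephx1 in 33 of 38 and Nqo1 in 23 of 37. The value of Ephx1 was 0.22 (adjusted p = 0.893) with the mean of its probes. Its brightest probe had a value on only 6 of 8 linseed arrays, so on the rest that mean held only its dimmer probe. The 0.22 therefore mixes missing values with the change, and the dimmer probe differed in the same direction. The values of Nqo1 and Gsta1 were 0.15 (adjusted p = 0.999) and 0.51 (adjusted p = 0.128) with normexp.

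Lipid droplet genes rose as a group: 3 of 22 members rose and 0 fell, and adjusted over the list alone 5 rose. Their mean was 0.43 higher (adjusted p = 0.0168 with an estimated correlation, 0.0506 with slide as a fixed block), and higher in 5 of 5 slides. Beside Cidec, G0s2, an inhibitor of the triglyceride lipase ATGL, rose 1.86-fold (0.89 ± 0.13, adjusted p = 0.00217), and Gpd1, which makes glycerol 3-phosphate, rose 1.54-fold (0.63 ± 0.13, adjusted p = 0.0343; 0.0512 with slide as a fixed block and 0.0171 as a random one; call kept in 16 of 38 settings). Pparg, a lipogenic nuclear receptor, had a difference of 0.44 ± 0.19 (adjusted p = 0.428), the fatty acid transporter Cd36 one of 0.71 ± 0.21 (adjusted p = 0.168), and Cidea, a relative of Cidec, one of 1.34 ± 0.91 (adjusted p = 0.667). Plin2, a coat protein of lipid droplets, was tested only with marked spots kept (0.38 ± 0.14, adjusted p = 0.294). The mean of the adipocyte markers was also higher in 5 of 5 slides, though that list did not pass, and a shared source was not tested.

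Phospholipid synthesis and remodelling shifted slightly: 3 of 23 members rose and 0 fell, and adjusted over the list alone 5 rose. The mean was 0.098 higher (adjusted p = 0.0135 with an estimated correlation, 0.0506 with slide as a fixed block). Chpt1, which completes phosphatidylcholine synthesis, rose 1.44-fold (0.52 ± 0.12, adjusted p = 0.0407). The kinases of ethanolamine and choline, Etnk1 (1.29-fold, 0.36 ± 0.08, adjusted p = 0.0429) and Chkb (1.28-fold, 0.35 ± 0.08, adjusted p = 0.0493), rose as well. These calls lay near the threshold and held in 14, 12 and 10 of 38 settings; with slide as a fixed block Chpt1 (adjusted p = 0.0516) and Chkb (0.0562) did not pass, while with slide as a random block they did (0.02 and 0.0238).

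Few members of the lipoprotein and bile acid lists changed. Vldlr, the receptor for very-low-density lipoprotein, rose 2.55-fold (1.35 ± 0.20, adjusted p = 0.00217; 0.49 with normexp and 0.70 in the authors' values) and was the 1 called member of 25 in the lipoprotein list, by either adjustment; the list did not pass (mean 0.11, adjusted p = 0.14). In the bile acid list, 1 of 23 members rose and 1 fell by either adjustment, and the list did not pass (mean 0.014, adjusted p = 0.321). Abcc3, an exporter of bile acids and conjugates, rose 2.20-fold (1.13 ± 0.12, adjusted p = 0.000271, n = 6 linseed and 9 palm). Cyp7a1 fell from 2.14 ± 0.40 (SD, n = 10) on palm to 1.14 ± 0.58 (SD, n = 8) on linseed oil; its call held in 22 of 38 settings, and its adjusted p was 0.0536 with slide as a fixed block and 0.02 with slide as a random block.

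No member of the fatty acid synthesis list passed, over all genes or adjusted over the list alone, among 20 tested. Its mean was −0.23 (adjusted p = 0.0769), with higher values on linseed oil in 2 of 5 slides; the list passed in 15 of 36 other settings. Pyruvate kinase Pklr was the member with the smallest p (−0.55 ± 0.21, adjusted p = 0.342). The lipogenic regulator Srebf1 (0.096 ± 0.24, adjusted p = 0.936), the fatty acid synthase gene Fasn (−0.26 ± 0.43, adjusted p = 0.894) and the acetyl-CoA carboxylase gene Acaca (−0.21 ± 0.20, adjusted p = 0.787) did not pass; the sign for Srebf1 changed in some settings. Scd1, which desaturates stearate, was measured only with marked spots kept (−0.84 ± 0.20, adjusted p = 0.0552). Desaturation and elongation of polyunsaturated fatty acids had no called member of 9, 1 higher adjusted over the list alone, and did not pass (mean 0.064, adjusted p = 0.384). Fads1 differed by −0.16 ± 0.16 (adjusted p = 0.802) and Fads2 by −0.087 ± 0.19 (adjusted p = 0.923), both desaturases of long-chain fatty acids; the sign of Fads2 changed in some settings. Hsd17b12, an elongation reductase, had a difference of 0.35 ± 0.09 (adjusted p = 0.0683; 0.0264 with slide as a fixed block and 0.0196 as a random one), and Elovl5, an elongase, 0.047 ± 0.21 with marked spots kept (adjusted p = 0.968).

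Cholesterol synthesis and uptake did not pass either (24 members, none called by either adjustment; mean −0.20, adjusted p = 0.138, past the threshold in 7 of 36 other settings). Squalene epoxidase Sqle differed by −1.02 ± 0.54 (adjusted p = 0.557). Glucose metabolism and insulin signalling had no called member of 22 by either adjustment (mean 0.028, adjusted p = 0.4), with glycogen phosphorylase Pygl at −0.17 ± 0.08 (adjusted p = 0.503).

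Beside Tff3, other genes were among the larger falls on linseed oil. Serpina12, the adipokine vaspin, was 2.83-fold lower (−1.50 ± 0.22, adjusted p = 0.00217; above background on 4 of 8 linseed arrays). Acpp, prostatic acid phosphatase, was 2.87-fold lower (−1.52 ± 0.26, adjusted p = 0.00652; above background on 4 of 8 linseed arrays), and Ptgds, a prostaglandin D synthase, 2.97-fold lower (−1.57 ± 0.32, adjusted p = 0.0277). Nat8, an N-acetyltransferase, was 2.02-fold lower (−1.02 ± 0.19, adjusted p = 0.0165). In the other direction, Adgrg2, an adhesion receptor, rose 3.61-fold (1.85 ± 0.29, adjusted p = 0.00302) but was above background on 3 of 10 palm arrays. With normexp background correction Adgrg2 (0.35, adjusted p = 0.364), Acpp (−0.43, adjusted p = 0.137) and Serpina12 (−0.39, adjusted p = 0.141) lost their calls, and Ptgds was at −0.49 (−0.68 in the authors' values) with its call kept in 31 of 37 settings. Krt23 also rose, 3.29-fold (1.72 ± 0.33, adjusted p = 0.017). The probe for Tff3 lies on chromosome 17 at 31262279 to 31262338 in mm9, and its mean was 4.18 ± 0.51 (SD, n = 10) on palm and 1.68 ± 0.87 (SD, n = 7) on linseed oil. The missing linseed value was a marked spot. With it kept the difference shrank to −2.19 ± 0.39, which places the array left out near the palm mean. The fall in Tff3 therefore did not extend to that mouse.

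The orosomucoids Orm1 (2.16-fold lower, −1.11 ± 0.17, adjusted p = 0.00787, n = 7 linseed and 6 palm) and Orm2 (2.04-fold lower, −1.03 ± 0.19, adjusted p = 0.0227, n = 8 linseed and 7 palm), plasma proteins of the acute phase, fell. They were the 2 called members of 25 in the acute phase list, against 3 lower adjusted over the list alone. The list's mean was −0.23, its call was lost with an estimated correlation (adjusted p = 0.702), and it was 0.60 higher on linseed oil within slide 1. Without palm replicate 3, the array with the highest neutrophil marker mean, it was −0.13 (adjusted p = 0.11); leaving out linseed replicate 1 or 8 or palm replicate 8 also ended the call, at −0.18, −0.21 or −0.18. Interferon response genes had no called member of 38, 5 lower adjusted over the list alone, and a mean of −0.21, lower on linseed oil in each of 5 slides. That call was lost with an estimated correlation (adjusted p = 0.366); the member with the smallest p was Ifi44 (−0.48 ± 0.14, adjusted p = 0.157).

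Female-biased liver genes had 2 of 12 members higher by either adjustment, Cyp3a16 and Acot3, and a mean of 0.42. The list's call was kept with fry (adjusted p = 0.0228) but lost with an estimated correlation (adjusted p = 0.366). The call was lost as well without linseed replicate 8 (0.37, adjusted p = 0.0635) or palm replicate 4 (0.35, adjusted p = 0.0551). It was also lost without slides 4 and 5. Male-biased genes under growth hormone and STAT5 had 1 of 20 lower by either adjustment, Serpina12, and did not pass (mean −0.027, median 0.0024, adjusted p = 0.496). In the circadian clock list 1 of 20 rose by either adjustment, Rora, a nuclear receptor (1.32-fold, 0.40 ± 0.09, adjusted p = 0.0489; 0.0565 with slide as a fixed block and 0.0251 as a random one; call kept in 9 of 38 settings), and the list did not pass (mean −0.052, adjusted p = 0.757).

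Other lists had no called member by either adjustment and did not pass. For endoplasmic reticulum stress (23 members) the mean was 0.082 (adjusted p = 0.127), with Sesn2, a stress-induced sestrin, at 0.36 ± 0.11 (adjusted p = 0.189). For the cell cycle (24 members) it was 0.0046 with a median of −0.049 (adjusted p = 0.805), and the repressor E2f8 was at 0.46 ± 0.25 (adjusted p = 0.582). Hepatocyte identity genes (23 members) had a mean of 0.036 (adjusted p = 0.576). Immediate early genes (23 members) had a mean of −0.037 (adjusted p = 0.804), with Nr4a2 at 0.68 ± 0.32 (adjusted p = 0.489). Heat shock proteins (21 members) had a mean of 0.098 (adjusted p = 0.14), with Hspb1 at 0.54 ± 0.19 (adjusted p = 0.275), and ribosomal proteins (57 members) one of 0.018 (adjusted p = 0.4), with Rps3 at 0.15 ± 0.08 (adjusted p = 0.595). The respiratory subunit Ndufa10 had the smallest p of the oxidative phosphorylation list (0.21 ± 0.08, adjusted p = 0.357).

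**Figure D2:**
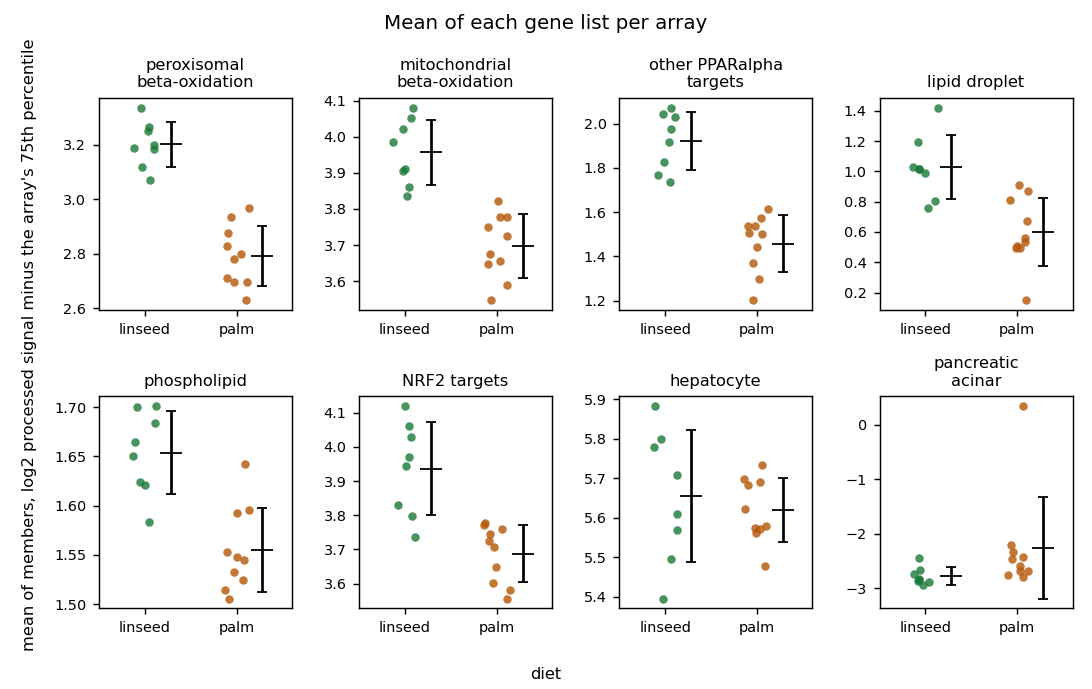
Each point is 1 array's mean over the tested members of a gene list, in log2 processed signal minus the array's 75th percentile (vertical axis, log2 units, scaled separately in each panel and not starting at 0), on linseed and palm oil; the bar marks the mean ± SD. Peroxisomal means are 3.20 on linseed and 2.79 on palm oil, hepatocyte means 5.65 and 5.62, and 1 palm array stands at 0.34 in the acinar panel.

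Markers of other cells and tissues were compared in the same way, and with an estimated correlation 0 of 9 marker lists passed, as with limma's fry. Pancreatic acinar markers (10 members) had a mean of −0.52, a call lost with an estimated correlation (adjusted p = 0.574) and without palm replicate 1 (−0.23, adjusted p = 0.0565). Their called member, by either adjustment, was the trypsin inhibitor Spink1 (2.1-fold lower, −1.07 ± 0.22, adjusted p = 0.0286; call kept in 26 of 38 settings). Neutrophil and myeloid precursor markers (12 members) had no called member by either adjustment and a mean of −0.31. The list's call was lost with an estimated correlation (adjusted p = 0.512), without palm replicate 3 (−0.16, adjusted p = 0.082) and without linseed replicate 7 (−0.19, adjusted p = 0.0883). It was also lost without slides 4 and 5. Their member with the smallest p was the protease gene Prtn3 (−1.21 ± 0.48, adjusted p = 0.363).

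The remaining marker lists, and the list of cytokines and chemokines, did not pass. Kupffer cell and macrophage markers (31 members) had a mean of −0.089 (adjusted p = 0.134; 0.00728 with slide as a fixed block and 0.0637 as a random one at the preset correlation, 0.768 as a fixed block with an estimated one), with Mpeg1 at −0.39 ± 0.15 (adjusted p = 0.342). Lymphocyte markers (16 members) had a mean of −0.016 (adjusted p = 0.635), with the antibody joining chain Jchain at 0.90 ± 0.31 (adjusted p = 0.268). Cytokines and chemokines (19 members) had a mean of −0.0022 (adjusted p = 0.769), with Cxcl13 at 0.99 ± 0.35 (adjusted p = 0.279). Stellate cell and matrix markers (30 members) had a mean of −0.014 (adjusted p = 0.635), with the collagen Col14a1 at −0.25 ± 0.10 (adjusted p = 0.391), and endothelial markers (24 members) 0.069 (adjusted p = 0.127), with Flt1 at 0.20 ± 0.09 (adjusted p = 0.467). None of these 5 lists had a called member by either adjustment. Cholangiocyte markers (17 members) had a mean of −0.087 (adjusted p = 0.217) and 1 called member by either adjustment, Krt23, which was higher. Adipocyte markers (7 members) had a mean of 0.19 but a test direction that was lower (adjusted p = 0.599). Their mean was higher on linseed oil in 5 of 5 slides, by 0.016 to 0.52. Orm1 was lower over all genes, and 1 member was higher and 1 lower adjusted over the list alone. Erythroid markers (9 members, none called by either adjustment) had a mean of −0.074 (adjusted p = 0.635), with the anion exchanger Slc4a1 at −0.47 ± 0.27 (adjusted p = 0.599).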

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

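The tests of explanations in this part were set after the results were seen; slide as a block, marked spots kept and leaving out each array had been chosen as settings before. Of 210 groups of arrays examined, 14 held an array far from the others of its diet; chance gives about 1 in 20. Palm replicate 3 accounts for 4 of them.

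The mean of the pancreatic acinar markers was 0.34 in palm replicate 1, against −2.20 in the next palm array. Among palm arrays, 9 of 10 tested members, each above background on at least 8 of the liver arrays, were highest there. The largest excesses were those of Sycn (5.94 above the median of the other palm arrays), Clps (4.54) and Cel (3.99). Pancreatic tissue in that liver piece is a candidate source of that signal and of part of the difference between diets: without the array the list's difference went from −0.52 to −0.23 (adjusted p = 0.0565), and 0 of the members stand in another list. The list was lower on linseed oil in 5 of 5 slides (−1.73 to −0.074), 4 of them without that array, so the rest of the difference stays open. The same source is argued against for Spink1, which was not highest in that array and differed by −1.02 ± 0.22 without it, against −1.07 ± 0.22 with it; its call ended (adjusted p = 0.0575) in a fit that called fewer genes (66). No biological explanation of the array's acinar signal was tested.

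The lists of peroxisomal, mitochondrial and other PPARalpha-linked genes were higher on linseed oil. A slide effect is argued against, since with slide as a fixed block the largest adjusted p of the 3 lists was 0.0288 with an estimated correlation, and each list was higher within 5 of 5 slides. The loss of marked bright spots is argued against by an adjusted p of 0.0201 with those spots kept. A larger hepatocyte share is argued against because the upper 95% limit of the hepatocyte list's difference, 0.162, lay below the least raised of the lists, 0.26. A response to the diet may therefore be proposed as a hypothesis, found and examined on the same arrays.

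Cyp3a41b, Cyp3a16, Cyp3a11, Cyp3a59 and Cyp3a57 rose on linseed oil. A slide effect is argued against for the 4 others by their smallest difference within a slide, 1.36. For Cyp3a57 slide as the whole cause is argued against by a difference of 0.52 ± 0.12 with slide as a fixed block (0.53 ± 0.12 without), higher in 4 of 4 slides; its call passed with slide as a random block (adjusted p = 0.0205) and narrowly missed with the fixed one (adjusted p = 0.0618, over all settings 0.0183 to 0.425). A single transcript read alike by all probes is argued against for Cyp3a59, whose change was −0.84 ± 0.098 relative to that of Cyp3a16, and for Cyp3a11, at −0.29 ± 0.090. Probes that read 1 transcript with unequal response would also differ, and probe sequences were not checked. A shared transcript read unequally and partial sharing of signal therefore stay open. For Cyp3a41b and Cyp3a16 the changes differed by 0.014 ± 0.079, so a shared transcript cannot be told apart from like regulation.

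Other arrays stood apart from their diet group in single values. The 75th percentile of the processed signal was 124 in palm replicate 3, the lowest of its group. In the same array Tff3 (5.34), Prtn3 (−0.32) and the mean of the neutrophil markers (1.49) were the highest. Palm replicate 4 was highest in Ephx1 (6.95) and in the endoplasmic reticulum stress list (2.11). Palm replicate 10 was highest in Cidea (0.75), palm replicate 8 in Pdk4 (−0.44), and palm replicate 2 lowest in Ifi44 (−1.85). Linseed replicate 2 was lowest in Cpt1a (4.44) and highest in G0s2 (4.74). Linseed replicate 8 was highest in Fasn (2.24), and linseed replicate 5 lowest in Slc4a1 (−5.33).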

How the results depend on the processing

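Scaling over unmarked spots and leaving out slides 4 and 5 or slide 1 were chosen after seeing the data. Counts of called genes (in all, higher, lower on linseed oil), against 121, 91 and 30, were 68, 58 and 10 with normexp, 44, 36 and 8 with no filter on dim probes, 200, 146 and 54 with slide as a random block, 63, 45 and 18 at 1.5-fold or more, 42, 30 and 12 with the percentile over unmarked spots, 21, 19 and 2 without slides 4 and 5, and 30, 23 and 7 without slide 1. Fewer arrays enter those 2 fits and more genes the unfiltered one (31137); the other causes were not tested. Normexp also moved the split between higher and lower. Of the 121 genes, 63 stayed called with normexp, 41 over unmarked spots, 20 without slides 4 and 5 and 30 without slide 1. Leaving out each array in turn gave 51 to 143 genes, 39 to 105 higher and 12 to 38 lower; counts moved by over 1.5 times without linseed replicate 2 (63), 3 (60), 5 (51) or 7 (62), or palm replicate 1 (66), 5 (63), 6 (78), 9 (64) or 10 (71). The other settings, the replicate number as a block aside, stayed between 100 and 149. Cyp3a41b, Cyp3a16, Cyp3a11 and Cyp3a59 kept their call in 38 of 38 settings, but Cyp3a57 in 11; Rora kept it in 9, Chkb in 10, Etnk1 in 12, Chpt1 in 14, Gpd1 in 16 and Cyp7a1 in 22. No named gene that was called changed sign in a setting with a test; within slide 5, Krt23 (−0.095) and Hsd17b6 (−0.064) did.

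Lists called at the preset correlation, 13 (9 higher, 4 lower), were 22 (16 higher, 6 lower) with normexp and 16 (7 lower) with no dim filter, but 6 with an estimated correlation (6 higher, 0 lower) and 8 with fry. Marker lists, 2 at the preset correlation, were 3 with normexp, with no dim filter, with slide as a fixed block, with replicate number as a block and without slide 1, and 0 with an estimated correlation or fry. Leaving out each array gave 11 to 17 lists, 9 to 11 higher, 2 to 6 lower, and 1 to 3 marker lists. The peroxisomal, mitochondrial, other PPARalpha, lipid droplet, phospholipid and NRF2 lists kept direction and call in 36 of 36 settings. Among these, only the estimated correlation and fry did not use the preset correlation. At that correlation 31 of 100 regroupings of the arrays gave as many lists as the real 13. Many settings left out 1 array each, so they are not independent. With slide as a fixed block and an estimated correlation together, which is not among the 36, the NRF2 (adjusted p = 0.124), lipid droplet (0.0506) and phospholipid (0.0506) lists did not pass. The acute phase list reversed within slide 1 (0.60), the neutrophil list within slides 1 (0.16) and 5 (0.39), and oxidative phosphorylation within slides 2 (−0.055) and 5 (−0.014); causes were not tested. At the preset correlation, leaving out linseed replicate 5, 6 or 8, or palm replicate 2, 4, 8, 9 or 10 took fatty acid synthesis past the threshold (−0.24 to −0.33), and linseed replicate 5 or 8, or palm replicate 2, 4 or 8 cholesterol synthesis (−0.27 to −0.29). Linseed replicate 2 or 8 or palm replicate 4 did so for endoplasmic reticulum stress (0.11 to 0.13), linseed replicate 4 or palm replicate 1, 9 or 10 for Kupffer cell markers (−0.13 to −0.19), linseed replicate 5 or 8 or palm replicate 4, 5 or 8 for endothelial markers (0.094 to 0.10), linseed replicate 2 or palm replicate 4 for heat shock proteins (0.16, 0.13), and linseed replicate 1 for ribosomal proteins (0.060). Without slides 4 and 5 the acute phase list was at −0.034 (adjusted p = 0.673, range over its settings 5.51e-06 to 0.702). The female-biased and neutrophil lists lost their calls there as well. With the replicate number as a block, fitted only on arrays whose number occurs in both diets, 18 genes passed (15 higher, 3 lower) and 15 lists (6 lower). Whether the numbers pair the mice could not be told. Residuals of same-numbered arrays correlated from −0.23 to 0.49, 5 of 8 pairs were over 0.1, and 2 linseed arrays were best matched by their own number. But 6 of the 8 pairs shared a slide, and residuals of arrays on the same slide correlated at a median of 0.26. With normexp 12 named genes lost their calls, namely Adgrg2, Acpp, Serpina12, Spink1, Acot2 (0.15), Etnk1, Chkb, Gsta1, Nqo1 (0.15), Rora, Gna14 and Cyp3a57. Vldlr (0.49) and Ptgds (−0.49) kept theirs at smaller differences. That setting adds an offset of 50 to every signal, against a 75th percentile of 117 to 204, which by itself shrinks the differences of dim genes. A lost call there therefore does not tell the correction from the offset. Signal over background limits genes such as Adgrg2, Acpp and Serpina12, which were above background on 3 or 4 arrays of a diet.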

Other observations

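In this part, the splits of the arrays had been set before the results were seen, except those within slides, which were added after, as were the hypothesis and its test. Further members of the peroxisomal and other PPARalpha lists, chosen for mention after their values were seen, were higher on linseed oil. Cyp4a32 rose 2.48-fold (1.31 ± 0.20, adjusted p = 0.00302), though the probe for Cyp4a10 also lists it and shared signal was not checked. The acyl-CoA thioesterases Acot5 and Acot4 rose 2.61-fold (1.38 ± 0.29, adjusted p = 0.032; 0.77 with normexp; call kept in 28 of 38 settings) and 1.68-fold (0.75 ± 0.13, adjusted p = 0.00948). Vnn1, a pantetheinase that recycles the precursor of coenzyme A, rose 2.24-fold (1.17 ± 0.20, adjusted p = 0.00676), Aldh3a2, a fatty aldehyde dehydrogenase, 1.92-fold (0.94 ± 0.14, adjusted p = 0.00217), and Retsat, retinol saturase, 1.89-fold (0.92 ± 0.16, adjusted p = 0.0089).

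Outside those lists, also chosen after their values were seen, Gsta2, a glutathione transferase, rose 2.12-fold (1.08 ± 0.24, adjusted p = 0.0394) and Hsd17b6, a steroid dehydrogenase, 2.30-fold (1.20 ± 0.26, adjusted p = 0.0375); these calls held in 18 and 19 of 38 settings. Gpat3, a glycerol 3-phosphate acyltransferase, rose 2.26-fold (1.18 ± 0.18, adjusted p = 0.00254), and the solute carrier Slc35f2 2.56-fold (1.36 ± 0.20, adjusted p = 0.00217; 0.54 with normexp and 0.73 in the authors' values). The G protein subunit gene Gna14 was 1.96-fold lower (−0.97 ± 0.16, adjusted p = 0.00553; call lost with normexp, at −0.34 with adjusted p = 0.111), and Nat8f5, a relative of Nat8, 1.94-fold lower (−0.96 ± 0.19, adjusted p = 0.0273; call kept in 27 of 38 settings).

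The 18 arrays were regrouped into 8 and 10 in 100 splits, the real one included. For the count of genes, 1 of the 100 splits gave as many as the real 121, and the highest other split gave 1, so chance is an unlikely source of that count. The splits used only the scaling that gave 121 genes, and they test the count, not single genes. With an estimated correlation, 1 of 100 gave as many lists as the real 6, with a highest other of 1, and chance is unlikely there too. With the preset correlation, 31 of 100 gave as many lists as the real 13 (highest other 21), and 75 of 100 gave as many marker lists as the real 2 (highest other 6), so chance cannot be excluded for these counts. Those splits do not keep the balance of the diets over slides, so 100 of the 1944 that keep it, the real one included, were also fitted. As many genes came from 1 of these 100 (highest other 2), and as many lists with an estimated correlation from 1 (highest other 4), so chance is an unlikely source of these counts within slides too. With the preset correlation 41 of 100 gave as many lists (highest other 20) and 88 as many marker lists (highest other 7), so chance cannot be excluded.

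A hypothesis, formed after the female-biased list had been seen to be higher on linseed oil, was that the male pattern of liver expression might be reduced there. The female-biased list, with 12 of 30 members tested, was 0.42 higher with a median of 0.26. Its call was kept with fry (adjusted p = 0.0228). It was lost with an estimated correlation (adjusted p = 0.366) and without linseed replicate 8 or palm replicate 4 (0.37 and 0.35) or slides 4 and 5. Its called members, Cyp3a16 (2.31) and Acot3 (1.91), also stand in the xenobiotic and peroxisomal lists, so its mean is not separate from those findings. The male-biased list, with 20 of 29 members tested, differed by −0.027 between the diets, with a lower 95% limit of −0.21. A loss as large as the female-biased mean is argued against by that limit. A loss as large as the female-biased median, 0.26, lay outside that limit too. The rule set for this test also asked for the members' median minus their SD (0.41) to exclude it, which failed. That SD is the spread between genes, not the precision of the list's mean. With marked spots kept, 26 male-biased members had a mean of −0.087 (adjusted p = 0.107) and 13 female-biased members one of 0.62. No such limit was taken there, so the hypothesis cannot be told apart from no loss.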
